A study of Mus musculus with 8 samples.

How the data were processed

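Liver RNA was extracted with RNeasy columns, per the labels' protocols, and 200 ng of it was depleted of ribosomal RNA and made into directional MGIEasy libraries. Per the submitters' processing notes, Trimmomatic 0.38, Bowtie2, RSEM and edgeR were used with the mouse build mm10, without a stated role or order; the strand setting of the counting is not given in the sources used here. Per the labels, 4 libraries come from control mice and 4 from MOCA-treated mice, each numbered as a separate mouse. The strain label and the series description name F1-TKm30 mice on the NOG background, while the treatment label names C57BL mice; the former is used here.

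The authors deposited a single table of scaled signal per gene (normalised counts), with 15210 genes and 1 column per mouse, and no raw counts were used. In it 100% of the values were whole multiples of 1 step per column within 0.001, so whole reads could be recovered. The step is 1 read, worth 0.0581 to 0.0648. The factor per column equals the TMM factor recomputed with edgeR from the recovered reads (largest difference 0). The deposited values are therefore TMM-scaled CPM; column sums differ between libraries. Each listed gene has at least 8 reads over the 8 libraries. Libraries hold 15024945 to 17101844 reads. The ribosomal RNA precursor Rn45s takes 3.29% to 3.98% of reads and Alb 5.89% to 7.01%. Xist was between 989 and 1388 in all 8 libraries and 0 of 4 Y-linked genes were listed. No replicate pair agreed within sampling noise: chi-square per degree of freedom over genes was 13.7 to 30.0. Number of columns not used: 0.

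The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes with trend, MOCA against control, and no covariate. Genes with a value of at least 1 in 4 or more of the 8 libraries were tested (12008; 3202 were left out), and Benjamini-Hochberg adjusted p under 0.05 made a call. The design had allowed for normalised values; the unit found required no other main test. Gene lists were tested with camera, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 of 42 lists with at least 5 tested members, and again with an estimated correlation and with fry. The score of a list in a mouse is the mean over its tested genes of the log2 difference from the control mean. As an alternative chosen after seeing the data, the count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. The edgeR test called 81 genes, 78 of them shared with limma.

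The gene lists, the tests of single genes and of lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among called genes with no overlap between the groups and a mean of at least 5. It adds up to 4 members of each list with the smallest p, and 15 genes of interest whatever their change. From the lists that camera called 4 members were tabulated and from the others 2, a choice made after the calls were known. A gene outside the rule is named where a count or feature calls for it, and was then chosen after its values were seen.

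Other settings chosen in advance were pseudocounts of 0.25 and 4, other filters, 3 rescalings, eBayes without trend or robust, sample weights, a replicate block, leaving out each mouse in turn, a stricter adjusted p of 0.01 and a fold change of at least 2. Positions and genomic spans come from RefSeq gene records of the mm10 assembly, matched by symbol for 99.7% of the tested genes; spliced length and GC content come from GENCODE transcripts. The limma test was tested on simulated reads for the 12008 genes with 200 changed genes. For MOCA against control it recovered 55.5% of the genes changed 1.5-fold, 91% of those changed 2-fold and 99% of those changed 3-fold. These were 111, 182 and 198 genes, with 9, 10 and 20 false calls beside them. The false calls thus made up more than 5% of the calls at each fold change. None of 36 random lists was called by camera in each simulation. The simulated genes varied independently, whereas the estimated correlation within real lists reached 0.79 (interferon-stimulated genes). The simulations therefore do not show how often camera calls a correlated list falsely.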

Results

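RNA was measured in the livers of 8 female F1-TKm30 mice, a line of the immunodeficient NOG background that carries a mutant herpes simplex virus thymidine kinase under the liver transthyretin promoter. Control mice (n = 4) received no test compound, and the other 4 mice received MOCA, an aromatic amine used to cure polyurethane, at 0.05% for 4 weeks; the route is not given in the sources used here. The mice were 17 or 21 weeks old, and no label ties an age to a mouse. Each mouse gave 1 library, with 15024945 to 17101844 reads assigned to the 15210 listed genes. Each of the MOCA libraries (15024945 to 15970453 reads) was shallower than each of the control libraries (16077424 to 17101844). Values below are TMM-scaled CPM (reads scaled to library size by the authors), where 1 read was worth 0.0581 to 0.0648, given as mean ± SD over 4 mice. Fold changes are MOCA over control on the log2(value + 1) scale, which understates the change of genes with low values, and positions are on mm10.

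Of 12008 genes tested, 48 were higher and 32 were lower in MOCA livers than in control livers (limma, Benjamini-Hochberg adjusted p under 0.05), among the higher ones the cytochromes P450 Cyp2b10 and Cyp2c29, 2 glutathione S-transferases and 5 genes that p53 activates. With a fold change of at least 2 required as well, 8 were higher and 5 were lower. Cyp2b10, a phenobarbital-inducible P450 (chromosome 7, 25897658 to 25926624), rose from 37.7 ± 11.3 to 142 ± 26.8, a log2 fold change of 1.92 (SE 0.22, adjusted p = 0.00468). Ly6a, a cell-surface protein also known as Sca-1 (chromosome 15, 74994877 to 74998031), rose from 18.9 ± 3.97 to 78.7 ± 45.8 (log2 fold change 1.83, SE 0.34, adjusted p = 0.0371), with MOCA mice spread from 33.8 to 137. Pctp, which binds phosphatidylcholine, rose by 1.08 (SE 0.21, adjusted p = 0.044), Slc10a2, a sodium-dependent bile acid transporter, by 0.88 (SE 0.13, adjusted p = 0.0131) and the kinase Ikbke by 0.87 (SE 0.11, adjusted p = 0.00833). In all 80 called genes the 4 MOCA values lay outside the range of the 4 control values; this held for 10.5% of the tested genes, against 2.86% by chance.

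The number of calls depended on which mice entered. Without control replicates 1, 2, 3 and 4 in turn, 45, 47, 29 and 40 genes were called, and without MOCA replicates 1, 2, 3 and 4 in turn 77, 42, 56 and 39. Of the 80 genes, 23 were called in all 8 of these fits, among them Phlda3, Eda2r, Ccng1, Zmat3, Cyp2b10, Cyp2c29, Aox1, Slc10a2 and Ikbke, and 11 in none. Ly6a was called in 1 of the 8, Pctp, Gstm3 and Gstm4 in 3 each. With eBayes without trend 59 of the 80 calls were kept, and with robust eBayes 75. Of the genes that the rule names, Ly6a, Pctp, Gstm4, Socs2, Slco1a4 and Uros were not called with eBayes without trend. With robust eBayes Ly6a, Gstm3, Pctp, Csad and Socs2 were not called. The highest adjusted p among these named genes was 0.121, for Ly6a. Pctp was also not called with a pseudocount of 4 or with sample weights. Without a filter on low values 74 of the 80 calls were kept, and of the genes that the rule names Uros and Pigr were not called. The split of 48 higher and 32 lower became 132 and 39 with columns scaled to equal sums, and 46 and 47 with upper quartile scaling.

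Several p53 target genes rose. Of the 26 tested members of the list, 5 were higher in MOCA livers, 0 were lower and 21 did not pass, and 22 had a positive and 4 a negative log2 fold change; adjusted over the list alone, 13 were higher and 0 lower. In this list edgeR called 5 and DESeq2 8. Phlda3, an inhibitor of AKT signalling (chromosome 1, 135766085 to 135769134), rose from 1.08 ± 0.143 to 5.47 ± 0.487, a log2 fold change of 1.63 (SE 0.11, adjusted p = 0.000101). Eda2r, a receptor of the tumour necrosis factor receptor family (chromosome X, 97333837 to 97377234), rose from 3.81 ± 0.697 to 12.5 ± 1.42 (log2 fold change 1.49, SE 0.12, adjusted p = 0.000312). Ccng1, cyclin G1 (chromosome 11, 40748552 to 40755309), rose from 45.5 ± 2.39 to 91.0 ± 7.28 (log2 fold change 0.98, SE 0.08, adjusted p = 0.000217). The RNA-binding protein gene Zmat3 rose by 0.71 (SE 0.09, adjusted p = 0.00661), and the nuclease gene Aen, named after its values were seen, by 0.53 (SE 0.09, adjusted p = 0.027); Aen was called in 1 of the 8 fits that left out a mouse. Over the list, camera gave an adjusted p of 8.02e-10 with a preset correlation. The adjusted p was 0.058 with an estimated correlation, and fry gave 0.00109.

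Other p53 targets that are often measured did not pass the test. Cdkn1a, which encodes the cell cycle inhibitor p21, was 60.6 ± 15.5 in control and 107 ± 46.5 in MOCA livers (log2 fold change 0.72, SE 0.31, adjusted p = 0.266); the MOCA mice had 160, 103, 116 and 47.2. Mdm2, the ubiquitin ligase of p53, was 29.2 ± 0.839 and 35.3 ± 2.74, with every MOCA value above every control value and an adjusted p of 0.126. Gdf15, a secreted stress-response factor, was 24.4 ± 9.54 and 46.5 ± 12.9 (adjusted p = 0.126), and Btg2 was 24.4 ± 12.1 and 48.8 ± 16.04 (adjusted p = 0.149). None of the 18 tested cell cycle genes was called (limma; 1 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2); Ccnd1, cyclin D1, was 26.4 ± 4.33 in control and 43.2 ± 10.04 in MOCA livers (adjusted p = 0.075), and the list did not pass (camera adjusted p = 0.221), though it passed without a filter on low values (0.0179).

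**Figure D1:**
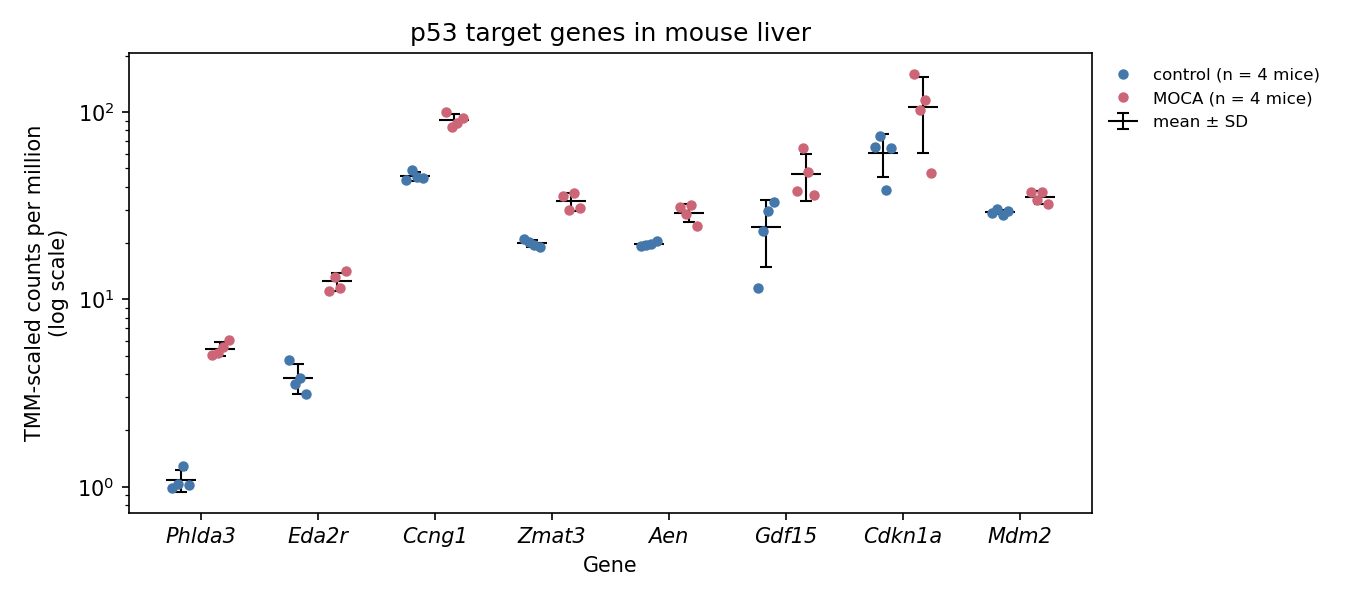
TMM-scaled CPM (log axis) of 8 p53 target genes in each control and MOCA liver; points are mice, black bars are the mean ± SD of 4 mice. Phlda3 rose from 1.08 to 5.47 with no overlap between groups, while Cdkn1a values of the groups overlapped.

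Among the genes of xenobiotic metabolism, targets of the nuclear receptors CAR and PXR differed from gene to gene. Of 20 tested, 2 were higher, 0 were lower and 18 did not pass; adjusted over the list alone, 5 were higher and 1 lower. Here edgeR called 2 and DESeq2 4. Besides Cyp2b10, Cyp2c29 (chromosome 19, 39287044 to 39330713) rose from 1321 ± 307 to 3190.1 ± 154 (log2 fold change 1.30, SE 0.15, adjusted p = 0.00534). Cyp3a11, a typical PXR target, was 4548 ± 818 and 4595 ± 1050 (log2 fold change 0.0021, SE 0.18, adjusted p = 0.996), with a sign that turned under median of ratios and upper quartile scaling. Cyp2a5 was 340 ± 127 and 396 ± 96.8 (adjusted p = 0.62). The list as a whole had a camera adjusted p of 0.0215. Its adjusted p was 0.791 with an estimated correlation, and 0.0981, 0.0631 and 0.113 without control replicate 1, control replicate 4 and MOCA replicate 1. The list shares 5 genes with the female-biased liver genes, of which Cyp3a41a, Cyp3a16 and Cyp3a44 had log2 fold changes of 1.48, 1.73 and 1.09 with adjusted p of 0.478, 0.447 and 0.522. P450 genes of 1 subfamily are similar in sequence, and how the counting split reads between them is not given in the sources used here.

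Of 24 tested NRF2 targets, the antioxidant and conjugation genes, 3 rose, 0 fell and 21 did not pass, and 22 had a positive log2 fold change; adjusted over the list alone, 14 were higher and 0 lower. Of these targets edgeR called 3 and DESeq2 10. Gstm3 (chromosome 3, 107963696 to 107969174) rose from 58.0 ± 22.9 to 146 ± 34.99 (log2 fold change 1.36, SE 0.23, adjusted p = 0.027), Gstm4 rose from 48.9 ± 11.8 to 89.1 ± 11.3 (0.88, SE 0.16, adjusted p = 0.0328), and aldehyde oxidase Aox1 from 84.7 ± 3.62 to 127 ± 7.95 (0.58, SE 0.07, adjusted p = 0.00534). Nqo1, a quinone reductase and common marker of NRF2 activity, was 7.33 ± 1.57 and 10.6 ± 1.46 (adjusted p = 0.123), and Gsta1 was 1.30 ± 0.497 and 4.31 ± 1.97 (adjusted p = 0.0626). The heme oxygenase Hmox1 (log2 fold change 0.12) and Gclm, a subunit of the enzyme that begins glutathione synthesis (0.04), had adjusted p of 0.666 and 0.844. Camera gave the list an adjusted p of 2.58e-09. The adjusted p was 0.207 with an estimated correlation, and 0.0308 with fry.

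The glutathione S-transferases, 7 of which are also NRF2 targets here, had 2 higher, 0 lower and 19 not called among 21 tested, and 9 higher when adjusted over the list alone; edgeR called 2 and DESeq2 6. Their camera adjusted p was 5.2e-05, and the adjusted p was 0.791 with an estimated correlation. Some Gstm and Gsta genes are close paralogs, and how the counting split reads between them is not given, so the value of a single member is uncertain.

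Targets of the aryl hydrocarbon receptor showed no common direction. None of the 7 tested was called over all genes by limma, 4 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0; adjusted over the list alone, 2 were higher and 2 lower. Cyp1a2 was 418 ± 50.1 in control and 406 ± 45.0 in MOCA livers (log2 fold change -0.04, SE 0.11, adjusted p = 0.884), a sign that turned with equal column sums. Cyp1a1 (0.508 ± 0.193 and 0.35 ± 0.2) and Cyp1b1 (0.545 ± 0.196 and 0.671 ± 0.42) were below the minimum for testing. Tiparp, a target that limits the receptor, was 15.98 ± 2.16 and 12.1 ± 0.866, with every MOCA value below every control value and an adjusted p of 0.12. The list had a camera adjusted p of 0.939; its median log2 fold change was 0.01 and its mean -0.0071, and the median turned negative with upper quartile scaling.

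Among other conjugating enzymes, none of 17 UDP-glucuronosyltransferase genes and none of 13 sulfotransferase and N-acetyltransferase genes was called by limma or edgeR, with 6 and 3 at an unadjusted p under 0.05 and 2 and 1 called by DESeq2; their camera adjusted p were 0.221 and 0.0806. Nat2, an N-acetyltransferase of aromatic amines, was 9.13 ± 1.70 and 10.04 ± 0.482 (adjusted p = 0.588), Nat1 was 0.73 ± 0.087 and 1.08 ± 0.158 without a test, and Ugt1a6a was 124 ± 15.8 and 124 ± 12.9 (adjusted p = 0.972). Papss1, which makes the sulfate donor, was 9.70 ± 0.712 and 13.5 ± 1.68 (adjusted p = 0.08). The pericentral P450 Cyp2e1, which has other substrates, was 5988 ± 301 and 5055 ± 518 (adjusted p = 0.283).

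**Figure D2:**
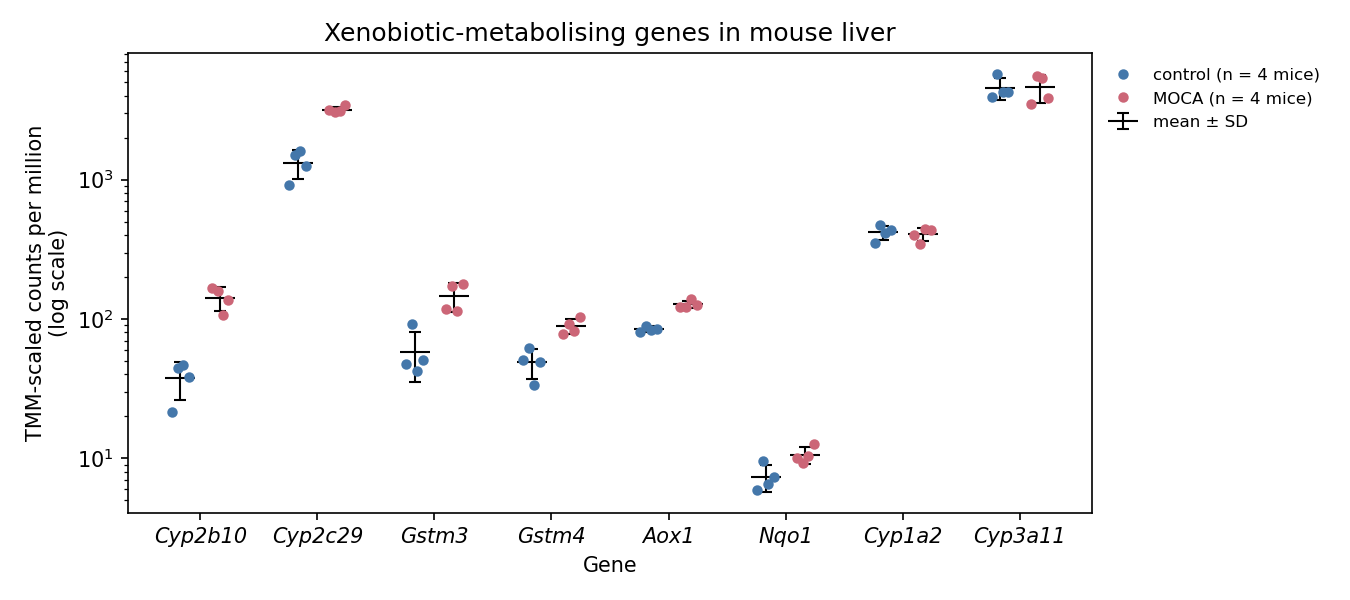
TMM-scaled CPM (log axis) of 8 genes of xenobiotic metabolism in each liver; points are mice, black bars are the mean ± SD of 4 mice. Cyp2b10 (37.7 to 142) and Cyp2c29 (1321 to 3190.1) separated the groups, whereas Cyp1a2 and Cyp3a11, whose signs depended on the scaling, overlapped.

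Among called genes with a mean of at least 5 over the 8 mice, the largest falls were in genes of several functions. Steap2, a metalloreductase (chromosome 5, 5664829 to 5694649), fell from 8.71 ± 1.38 to 2.97 ± 1.36 (log2 fold change -1.34, SE 0.20, adjusted p = 0.0152). Ntrk2, a neurotrophin receptor (chromosome 13, 58806472 to 59133970), fell from 33.0 ± 5.40 to 14.1 ± 3.70 (-1.19, SE 0.16, adjusted p = 0.0105). Csad, which catalyses a step of taurine synthesis (chromosome 15, 102176997 to 102205052), fell from 310.4 ± 52.4 to 153 ± 38.5 (-1.04, SE 0.18, adjusted p = 0.028). Smad9, a transducer of BMP signals, fell from 39.3 ± 6.71 to 19.3 ± 2.38, and Socs2, an inhibitor of growth hormone signalling, from 51.6 ± 10.5 to 25.9 ± 5.68 (adjusted p = 0.00778 and 0.0308). The remaining 5 of the 10 largest falls above that mean were Pard3b (-0.98), Wfdc2 (-0.93), Park2 (-0.93), Caln1 (-0.76) and Sptb (-0.73), with adjusted p of 0.0131, 0.0202, 0.0131, 0.039 and 0.0209. Ntrk2, Pard3b, Park2 and Smad9 were called in all 8 fits that left out a mouse, Steap2 in 6, Sptb in 5, Wfdc2 and Socs2 in 4, Csad in 3 and Caln1 in 1. Overlapping and antisense genes cannot be told apart where the strand setting of the counting is not given, as here.

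Secreted and transport proteins of hepatocytes fell in a few cases. Itih3, an inter-alpha-trypsin inhibitor chain (chromosome 14, 30908572 to 30923787), fell from 958 ± 30.1 to 603 ± 61.5 (log2 fold change -0.67, SE 0.09, adjusted p = 0.00778), and was the single call by limma and edgeR among 25 acute phase genes (2 by DESeq2; camera adjusted p = 0.0806). Pigr, the receptor that carries IgA into bile, fell from 2680.3 ± 230 to 1842 ± 134 (-0.54, adjusted p = 0.0344), the single call by limma, edgeR and DESeq2 among 14 periportal genes (camera adjusted p = 0.0769). The organic anion transporter Slco1a4 fell from 218 ± 23.02 to 149 ± 16.7 (-0.55, adjusted p = 0.0328), the single call by limma and edgeR among 15 transporters (2 by DESeq2; camera adjusted p = 0.723); Itih3 was called in all 8 fits that left out a mouse, Pigr and Slco1a4 in 2 each. Of 19 hepatocyte secretory and identity genes none was called by limma or edgeR (3 at an unadjusted p under 0.05, 4 by DESeq2), with a camera adjusted p of 0.0444 for lower values; Trf, transferrin, was 21030 ± 2065 and 16088 ± 1091 (adjusted p = 0.218), and Ttr, the gene whose promoter drives the transgene, was 4332 ± 503.7 and 4248 ± 330 (adjusted p = 0.938), a sign that turned with equal column sums. That list's adjusted p was 0.791 with an estimated correlation, 0.0803 without a filter on low values, 0.111 with the replicate block, and 0.103, 0.148, 0.1 and 0.232 without control replicates 2 and 4 and MOCA replicates 2 and 4. The 15 pericentral genes held no call (2 at an unadjusted p under 0.05, 0 by edgeR, 1 by DESeq2; camera adjusted p = 0.322); Lgr5 was 8.63 ± 2.19 and 5.52 ± 0.428 (adjusted p = 0.12).

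In cholesterol synthesis and lipogenesis no gene was called by limma or edgeR (5 of each at an unadjusted p under 0.05; 0 and 2 by DESeq2), although the camera test with a preset correlation gave adjusted p of 0.0158 for 24 cholesterol synthesis genes and 0.038 for 19 lipogenic genes, both toward higher values. For both lists the adjusted p was 0.795 with an estimated correlation, and without MOCA replicate 4 it was 0.232 and 0.287. Without control replicate 3 or 4 it was 0.137 and 0.128 for cholesterol synthesis, and without control replicate 1, 3 or 4 it was 0.0981, 0.171 and 0.0631 for lipogenesis. Lipogenesis also missed the threshold with equal column sums, sample weights and eBayes without trend (0.0552, 0.069 and 0.051). Fasn, fatty acid synthase, was 405 ± 59.0 and 633 ± 188, and Elovl6, a fatty acid elongase, was 47.9 ± 6.54 and 104 ± 54.6 (adjusted p = 0.126 and 0.0977). The 14 bile acid synthesis genes held no call by limma or edgeR (5 at an unadjusted p under 0.05, 1 by DESeq2) and their median (0.05) and mean (-0.11) differed in sign (camera adjusted p = 0.786); Cyp7a1, the rate-limiting enzyme, was 129 ± 71.0 and 43.5 ± 27.8 (log2 fold change -1.61, SE 0.52, adjusted p = 0.163). PPAR-alpha targets (27 genes), gluconeogenesis and glycogen genes (11) and urea cycle genes (8) held no call by limma, edgeR or DESeq2, with 3, 1 and 1 at an unadjusted p under 0.05 and camera adjusted p of 0.88, 0.164 and 0.88.

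Chaperones of the endoplasmic reticulum had higher values in 17 of 18 members, none of which was called by limma or edgeR (8 at an unadjusted p under 0.05, 1 by DESeq2); camera gave an adjusted p of 9.03e-06. The adjusted p was 0.791 with an estimated correlation. Pdia6, a protein disulfide isomerase, was 205 ± 34.5 in control and 307 ± 45.1 in MOCA livers (adjusted p = 0.0632), and Calr was 461 ± 72.7 and 620.0 ± 121 (adjusted p = 0.187). The mean log2 deviation of the list from the control mean was 0.81 in MOCA replicate 3, and 0.22, 0.30 and -0.06 in MOCA replicates 1, 2 and 4. Heat shock genes (12 tested), the integrated stress response (12; median -0.04, mean 0.03) and immediate early genes (14) held no call by limma or edgeR (3, 4 and 2 at an unadjusted p under 0.05; 1, 0 and 0 by DESeq2), with camera adjusted p of 0.162, 0.88 and 0.382. The 23 cytosolic ribosomal protein genes were lower in 20 members without a call by limma, edgeR or DESeq2 (4 at an unadjusted p under 0.05; camera adjusted p = 0.000485). That adjusted p was 0.791 with an estimated correlation. The ribosomal list's score was -0.157, 0.173, -0.062 and 0.046 in control replicates 1, 2, 3 and 4. In MOCA replicates 1, 2, 3 and 4 it was -0.140, -0.058, -0.101 and -0.156, so the lowest score was that of a control mouse.

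Of the fetal and liver tumour-associated genes, 8 were tested, 1 rose and 7 did not pass; adjusted over the list alone, 2 were higher, and edgeR called 1 and DESeq2 2. Krt18, a keratin of simple epithelia including hepatocytes (chromosome 15, 102028216 to 102032026), rose from 69.9 ± 8.23 to 106 ± 6.70 (log2 fold change 0.59, SE 0.09, adjusted p = 0.0161), and was lost only without MOCA replicate 2 among the fits that left out a mouse (adjusted p = 0.0509). Its partner Krt8 was 90.8 ± 14.7 and 146 ± 27.8 (adjusted p = 0.0619). Camera gave the list an adjusted p of 0.000798. The adjusted p was 0.135 with an estimated correlation, 0.126 without a filter on low values and 0.00904 with fry. Afp and Gpc3, which give the list its name, were below the minimum for testing.

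Sinusoidal endothelial markers were lower in 10 of 12 members (median log2 fold change -0.13, camera adjusted p = 0.00906), and Kupffer cell markers were higher in 12 of 13 (0.20, camera adjusted p = 0.00986); the adjusted p of each was 0.791 with an estimated correlation, and that of the Kupffer markers was 0.0631 without control replicate 4 and 0.229 without MOCA replicate 4. None of these genes was called by limma, edgeR or DESeq2, and 3 endothelial and 2 Kupffer markers had an unadjusted p under 0.05. Stab2, a scavenger receptor of sinusoidal endothelium, was 154 ± 14.6 and 129 ± 1.98 (adjusted p = 0.138). Stellate cell and matrix genes (17 tested) and cholangiocyte markers (8) held no call by limma or edgeR (3 and 2 at an unadjusted p under 0.05; 1 and 0 by DESeq2), with camera adjusted p of 0.433 and 0.115. Erythroid markers had a median of 0.63 over 6 tested genes, with none called over all genes by limma or edgeR and 3 by DESeq2; 5 had an unadjusted p under 0.05 and were higher when adjusted over the list alone (camera adjusted p = 0.000891). The adjusted p was 0.339 with an estimated correlation. Hba-a1, an alpha globin with a near-identical copy, was 161 ± 33.5 and 259 ± 45.7 (adjusted p = 0.0617). Of the heme and iron genes, 1 of 16 rose by limma, edgeR and DESeq2: Uros, of heme synthesis, from 6.39 ± 1.35 to 11.1 ± 1.43 (adjusted p = 0.0461), called in 1 of the 8 fits that left out a mouse; the list did not pass (camera adjusted p = 0.591).

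Interferon-stimulated genes had a camera adjusted p of 0.00296 toward higher values with none of 25 called by limma or edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2), and this rested on MOCA replicate 4, where the list's mean log2 deviation was 0.95; without that mouse the adjusted p was 0.806, and with sample weights 0.0603. With an estimated correlation the adjusted p was 0.795. Inflammatory cytokine genes (9 tested; median 0.06, mean -0.05), circadian clock genes (17), female-biased genes (20) and male-biased genes (14) held no call by limma or edgeR (3, 3, 2 and 4 at an unadjusted p under 0.05; 0, 0, 1 and 1 by DESeq2), with camera adjusted p of 0.591, 0.761, 0.221 and 0.164. Acute phase and periportal genes passed with equal column sums (0.0381 each) and in some fits that left out a mouse (lowest 0.00347, without MOCA replicate 2, and 0.00141, without control replicate 1). Lists that passed only when a mouse was left out were female-biased genes (0.0129 and 0.00328 without MOCA replicates 2 and 3), male-biased genes (0.0361 without MOCA replicate 1), sulfotransferases (lowest 0.00952, without MOCA replicate 3), heat shock genes (lowest 0.00971, without MOCA replicate 4), immediate early genes (lowest 0.0284, without MOCA replicate 1), UDP-glucuronosyltransferases (0.0358 without control replicate 2), gluconeogenesis genes (0.0289 without MOCA replicate 1), cholangiocyte markers (0.0325 without MOCA replicate 3) and PPAR-alpha targets (0.0497 without MOCA replicate 1, toward lower values). With a minimum value of 10, the CAR and PXR, cholesterol synthesis, lipogenesis, interferon and Kupffer lists did not pass (0.0808, 0.1, 0.1, 0.0885 and 0.0808). The lymphocyte (1 tested gene), neutrophil (2), monocyte (4), pancreas acinar (1) and adipocyte (2) lists had too few members above the minimum to be tested, and none of their members was called by limma, edgeR or DESeq2 or had an unadjusted p under 0.05. No mitochondrially encoded gene was listed, so that list was not analysed here. Across the 36 lists, 14 passed camera with a preset correlation, 3 passed fry, and 0 passed camera with an estimated correlation.

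**Figure D3:**
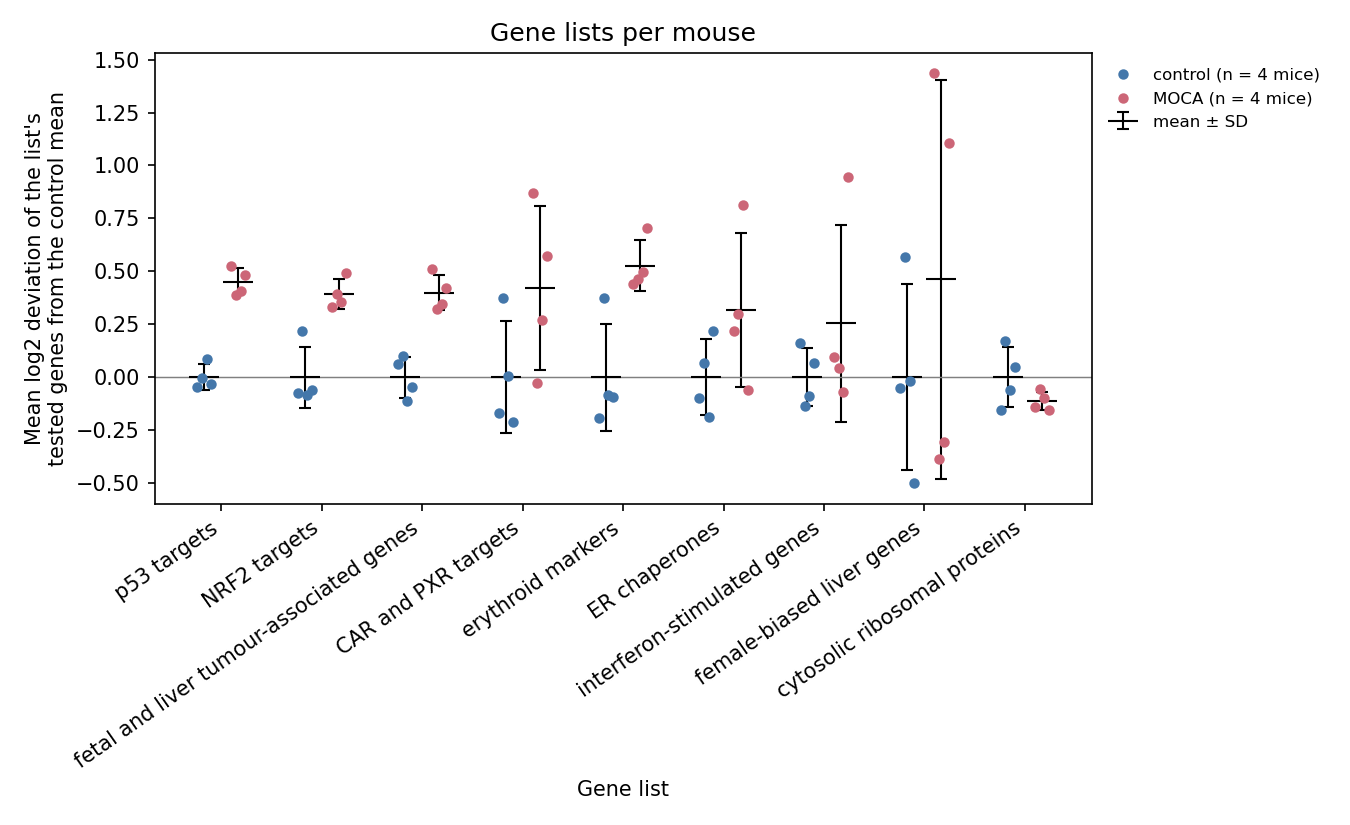
Mean log2 deviation of the tested genes of 9 lists from their control mean in each liver; points are mice, black bars are the mean ± SD of 4 mice. The p53 list lay between 0.39 and 0.52 in the MOCA mice and between -0.05 and 0.09 in the controls, while female-biased genes ranged from -0.38 to 1.43 within the MOCA group.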

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

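All values in this part were picked by a fixed rule that asks whether the highest or lowest of the 4 mice of a group stands far from the other 3 (Dixon's ratio at 95%), and no test was added after they were seen. Of 334 groups of 4 mice looked at, 16 met it, or 4.79%, where chance gives about 5%, so the number of such values is no more than chance gives. No explanation was weighed for them.

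Among single genes in control mice, Phlda3 was 1.30 in replicate 3 with the others between 0.988 and 1.03, still far below the lowest MOCA value of 5.03. Hsp90b1 was 513 in control replicate 3 with the lowest of the others at 622. Control replicate 2 had high values of Hba-a1 (211, the others from 143 to 145), Alas2 (16.04, the lowest other being 11.2) and Papss1 (10.8, the lowest other being 9.24). Serpina1c was 5948 in control replicate 4, and Mup20, a member of a family of near-identical genes, was 16.6 in control replicate 1.

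Among single genes in MOCA mice, Tiparp was 10.8 in replicate 3 with the others between 12.5 and 12.7, and Serpina1c was 4962 in the same mouse. Cd24a was 1.85 in MOCA replicate 1, and Npas2 was 22.3 in MOCA replicate 2.

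Among list scores, interferon-stimulated genes stood at 0.95 in MOCA replicate 4, against -0.07 to 0.10 in the other MOCA mice. NRF2 targets stood at 0.22 in control replicate 2, below each MOCA mouse (0.33 to 0.49). Matrix and stellate cell genes stood at -0.14 in control replicate 2, cholangiocyte markers at 0.15 in control replicate 4 and clock genes at 0.15 in MOCA replicate 1.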

How the results depend on the processing

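The edgeR and DESeq2 tests in this part were chosen after the data were seen; the rest was planned. Each of the 80 calls kept its sign in every alternative in which the gene was tested. The groups did not overlap in any of these genes, so leaving out a mouse could not turn a sign. For the gene counts, the 35 splits of the 8 mice into 4 and 4 argue against a chance division. For the number of lists they do not. A share of 1 of 35 is the smallest that these splits can give, so chance is not excluded. The splits also cannot separate MOCA from another difference between the groups, such as age or library depth. Only the real split (1 of 35) gave as many called genes, as many higher or as many lower, and the highest other split called 1 gene. Of the 35 splits, 13 gave 14 or more lists, the real split included, and the highest other gave 18. By list, the real split gave the smallest camera p for p53 targets and fetal genes (1 of 35 each), was among 2 of 35 for NRF2 targets, and among 4 to 27 of 35 for the other called lists. With 36 lists ranked in this way, a rank of 1 of 35 can arise by chance for a list.

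Against 80 genes called (48 higher, 32 lower), equal column sums gave 171 and 132 higher, and robust eBayes gave 53 lower. A minimum value of 10 gave 18 lower and 7 lists, with fewer genes tested (7653). An adjusted p under 0.01 gave 13 genes (10 higher, 3 lower), and a fold change of at least 2 gave 13 (8 and 5). DESeq2 gave 420 (220 and 200), of which 77 were among the 80. Leaving out 1 mouse gave 29 to 77 genes, 21 to 42 higher, 8 to 35 lower and 9 to 18 lists, lowest without control replicate 3 for genes and control replicate 4 for lists; fewer mice remain in these fits. An estimated correlation left 0 lists (14 with the preset one), and fry 3. The other counts stayed within 1.5 times, though with eBayes without trend 59 of the 80 calls were kept. Except where named, the cause was not tested.

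The replicate block gave 30 genes (20 higher, 10 lower), 28 of them among the 80. The replicate numbers do not pair the mice: same-numbered mice correlated at -0.07, -0.0014, 0.04 and -0.04 in their deviations from the group means, and none correlated best with its own number. The block also uses up degrees of freedom.

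Signs of named genes turned only in values near 0, none called: Cyp3a11 at -0.0016 with median of ratios scaling and -0.010 with upper quartile scaling, Ugt1a6a at -0.0016 with upper quartile scaling, and Cyp1a2 at 0.013 and Ttr at 0.029 with equal column sums. Leaving out 1 mouse gave -0.10 to 0.12 for Cyp3a11, -0.056 to 0.068 for Ugt1a6a, -0.12 to 0.036 for Cyp1a2 and -0.10 to 0.038 for Ttr. The PPAR-alpha list, toward higher values in the main fit, passed toward lower values without MOCA replicate 1 (camera adjusted p = 0.0497, against up to 0.908 without another mouse). With equal column sums the medians of the transporter, urea cycle and integrated stress response lists also changed sign, and that of PPAR-alpha targets with the other 2 rescalings. Of 28 named genes that were called, 14 were called in all fits that left out a mouse. At this depth and number of mice, simulated 1.5-fold changes were recovered in 55.5% of cases.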

Other observations

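The genes named here lie outside the fixed lists or were grouped after their values were seen. The tests by matched genes, on non-hepatocyte markers and on fragile site genes were chosen after the pattern of long genes was seen. No test on gene span, the regression included, was among those fixed before the data were examined. Among other called genes, retinaldehyde dehydrogenase Aldh1a1 rose from 757 ± 89.5 to 1199 ± 123 and its close paralog Aldh1a7 from 126 ± 31.7 to 221 ± 31.4 (limma adjusted p = 0.0202 and 0.0366), and reads can be shared between them. Ly6e rose from 639 ± 55.3 to 1036 ± 94.2 (adjusted p = 0.00912), and Ddias, named for suppressing apoptosis after DNA damage, from 1.13 ± 0.243 to 3.92 ± 1.497 (adjusted p = 0.0202). Of plasma proteins, complement C4b fell from 2666 ± 327 to 1725 ± 111, coagulation factor F5 from 1249 ± 91.2 to 888 ± 67.3 and the peptidoglycan amidase Pglyrp2 from 88.8 ± 4.96 to 60.7 ± 7.89 (adjusted p = 0.027, 0.03 and 0.0273). Of the 8 fits that left out a mouse, Ly6e was called in 8, Aldh1a1 in 5, Ddias in 4, Pglyrp2 in 3, C4b in 2, and F5 and Aldh1a7 in 1 each.

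Female-biased liver genes differed strongly between mice of 1 group. Cyp3a41a was 2811 and 1578 in MOCA replicates 1 and 4 and 73.4 and 543 in MOCA replicates 2 and 3, while the 4 controls had 403, 704.2, 149 and 68.9. Cyp3a16 was 201 and 73.0 in MOCA replicates 1 and 4, against 1.81 and 7.26 in MOCA replicates 2 and 3. The list's score was 1.43, -0.38, -0.31 and 1.10 in MOCA replicates 1 to 4. All 8 mice are labelled female, and no label gives a stage of the oestrous cycle.

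Genes that fell in MOCA livers were often very long. Of the 32 lower calls, 15 spanned over 300 kb on mm10, against 1 of 48 higher calls (Exoc4, 725 kb) and 2.29% of all tested genes. They included Fhit (1612 kb), Park2 (1223 kb), Pard3b (1004 kb), Dpyd (871 kb), Large (539 kb) and Ntrk2 (327 kb). Fhit had 116 reads over the 4 control and 3 over the 4 MOCA libraries, a control-to-MOCA ratio of 37.1 after scaling (exact 95% interval 12.4 to 183, counting error only). Dpyd, which degrades pyrimidines, fell from 811 ± 57.3 to 596 ± 18.0 (limma adjusted p = 0.0273), and was called in 2 of the 8 fits that left out a mouse. A smaller shift was seen in the uncalled genes over 300 kb as a set, genes with low values included. For these 254 genes, the median log2 deviation from 10 matched genes of up to 100 kb each was 0.0052 ± 0.03 in control and -0.10 ± 0.03 in MOCA mice (n = 4 each, exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give).

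The regression argues against spliced length, GC content or expression level as the whole cause: with these in the regression the MOCA minus control difference of the slope on log10 span was -0.0452 (exact permutation p = 0.0286), against -0.0438 without them (p = 0.2). A lower share of endothelial, stellate, bile duct or Kupffer cells was weighed for the 15 called falls as a set. Their median per mouse differed by -0.788 (95% interval over mice -0.95 to -0.62) between MOCA and control. For the 7 with a mean of at least 5 it differed by -0.73 (-0.96 to -0.50). These genes were picked as called lower in these same mice, so both values and intervals are biased toward a fall. The more abundant markers of these cells, not picked by their change, differed by -0.12 (-0.23 to -0.01), 0.0013 (-0.23 to 0.24), -0.12 (-0.32 to 0.09) and 0.15 (-0.14 to 0.45). No marker set fell as far as the 15 genes, but the selection keeps this comparison from deciding the cause. Cell types without tested markers were not weighed. For the smaller shift of the uncalled genes such a lower share cannot be told apart, since sinusoidal endothelial markers had a median log2 fold change of -0.127 and cholangiocyte markers of -0.14, but stellate cell genes of 0.06 and Kupffer cell markers of 0.20. As a hypothesis, DNA adducts of the aromatic amine may hinder transcription over long genes. Among uncalled genes with a mean of at least 10 the adjusted slope difference was -0.0333 (exact permutation p = 0.2). With span alone it was -0.0292 (exact permutation p = 0.429). These values leave the hypothesis open, and show no clear shift with span among the more abundant uncalled genes. A fall specific to common fragile sites, where Fhit, Park2 and Large lie, also stays open. Only 4 of the 16 others listed here were tested, with a median of -0.203 (Wwox -0.66, Immp2l -0.30, Nbea -0.10, Dmd 0.10). That lies between the lower quartile (-0.24) and median (-0.09) of the other long genes. The list need not be complete, so some of those other long genes may also lie at such sites. Age (17 or 21 weeks) is tied to no mouse, and an age or litter difference between the groups was not tested.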
